A study of Homo sapiens with 6 samples.

How the data were processed

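The samples were 6 libraries of small RNA from MDA-MB-231 cells, 3 with a stably expressed Flag vector and 3 with Flag-PAK5, grouped and numbered by their titles. Per the labels' protocols, cells were infected with lentivirus and selected in puromycin, total RNA was extracted with TRIzol, adaptors were ligated to both ends, fragments in the size range of small RNAs were selected after PCR, and libraries were sequenced for 50 cycles on an Illumina NextSeq. Novoalign 2.07.11 is named in the submitters' processing notes. The genome build, the miRNA annotation release, the trimming and filters, and the way predicted entries were called are not given in the sources used here.

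The authors deposited 2 tables. Per the file headers, the first holds raw tag counts summed over all isoforms, with 1 line for each pair of mature miRNA and precursor, and its columns match the sample descriptions. Its 2333 lines hold 2225 mature names, of which 554 lines are predicted entries without an established name. The lowest value listed is 2, and blanks were taken as 0. A mature miRNA with several precursors (84 names) is listed once per precursor with largely the same tags, so the line with the highest total was kept for each. Summing all lines instead adds between 5.54% and 6.37% to a library's total. The second table holds a normalized score that the authors scaled to nearly equal totals, from 982184 to 985548 per library, and rounded to whole numbers. For lines of at least 10000 counts the median ratio of raw count to score was 6.64, 7.37 and 3.90 in Flag vector 1, 2 and 3, and 6.86, 6.44 and 5.39 in Flag-PAK5 1, 2 and 3. For lines of 10 to 100 counts it was 7.50, 8.67, 3.41, 8.00, 7.61 and 5.52 in the same order. Lines under 10 counts were blank in 72.4%, 74.9%, 0%, 76.1%, 77.4% and 53.7% of cases. Rounding each summed count at the ratio of its library would leave 51.6%, 51.1%, 0%, 53.8%, 52.8% and 41.2% blank, so part of the blanks goes with rounding, and the rest was not traced. That table was used only for 1 alternative.

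Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group with its minimum count of 10, the quasi-likelihood test, 2-sided, and Benjamini-Hochberg adjustment over 675 miRNAs at a threshold of 0.05. CPM values use library totals times TMM factors, which ran from 0.947 to 1.08. Lists of miRNAs were tested with camera (limma 3.58.1) at its preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 3 tested members. A list takes both arms of its precursors. Arm balance was tested with limma on log2 of 5p over 3p counts, each plus 0.5, for 134 precursors with both arms tested. Reads of near-identical family members and of miRNAs with equal mature sequences cannot be told apart in these counts, and 15 mature names share their counts in all 6 libraries with another name. Ratios of summed counts carry exact 95% counting intervals, and a group at 0 was given a floor of 3 counts per library. GENCODE release 29 (GRCh38) was used only for the names of host and neighbouring genes.

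The miRNAs named follow a rule fixed before the data were examined. It takes up to 8 rises and 8 falls by fold change among those past the threshold with a mean of at least 10 CPM and no overlap between groups, the 4 most abundant past the threshold in each direction, and the 5 most abundant of all. It adds the 3 members with the smallest p of each list that passed and of the metastasis lists, the let-7 family and the miR-200 family, the 5 smallest p-values in a direction with fewer than 5 calls, and the 3 precursors with the smallest p for arm balance. Other miRNAs were named after their values were seen.

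No libraries were duplicates: the lowest chi-square per degree of freedom between any 2 was 103. Deviations from the group mean correlated between libraries of the same number, with r of 0.307, 0.469 and 0.648 over miRNAs for numbers 1, 2 and 3. All lie above 0.1. Deviations from a group mean cancel out within the group, so the shared deviation of the libraries numbered 3 alone can raise the other r values. The values therefore show a link between the libraries numbered 3 and do not settle whether numbers 1 and 2 are pairs. Any pairing by number comes from the data alone, since the labels describe no shared batch or day. The test without the block was kept, as planned. Blocked values are given where they change a call of a miRNA or precursor named by the rule. For other miRNAs called only with the block, they are given for some. Flag-PAK5 1 correlated best with Flag vector 2, and each of the other libraries with the library of its own number.

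Alternatives covered the normalization, DESeq2 1.42.0, limma-voom, the authors' normalized values, filters on low counts, a robust fit, the replicate block, leaving out each library, an estimated correlation or fry for lists, and the pseudocount for arms. Alternatives added after seeing the data were summing precursor lines, leaving out predicted entries, merging names with equal counts, leaving out both libraries numbered 3, and leaving miR-199, miR-31, miR-10b and miR-363 out of the lists. The test was run on simulated counts for the 675 miRNAs with 200 of them changed: it recovered 28.4% of those changed 2-fold, 82.1% of those changed 4-fold and 95.5% of those changed 16-fold, and called 3 of 475 unchanged ones. The changed miRNAs were picked at random and counts were drawn independently, without the deviation shared by the libraries numbered 3. With so many changed, the adjusted threshold is easier to pass than in the data. The rates may thus overstate the power of the real comparison.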

Results

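Small RNA was sequenced from MDA-MB-231 cells, an established human line of triple-negative breast cancer, after stable lentiviral expression of either a Flag vector or Flag-tagged PAK5. PAK5 is a serine/threonine kinase of the p21-activated kinase family. The comparison asks which miRNAs differ between the cells with Flag-PAK5 and those with the Flag vector. Each group had 3 libraries, numbered 1 to 3. Summed tag counts were 6128451, 6815275 and 3630276 in Flag vector libraries 1, 2 and 3, and 6368630, 5957221 and 5034704 in Flag-PAK5 libraries 1, 2 and 3. Of 2225 mature miRNA entries, 1625 were listed in at least 1 library and 675 entered the test, of which 472 carry established names and 203 are predicted entries. The most abundant miRNA, miR-21-5p, took 34.1% ± 2.69 (SD, n = 3) of the counts in Flag vector cells and 37.3% ± 1.24 (SD, n = 3) in Flag-PAK5 cells. Both libraries numbered 3 stood apart on the first principal component, which held 45.7% of the variance, and the second component (31.7%) parted the groups. Nothing in the labels states that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Separate infections are not stated either. If each group came from 1 infection, differences that arose in infection or selection cannot be told apart from an effect of PAK5. Counting intervals and floors cover counting error only, since the tags carry no described molecular identifiers.

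A small set of miRNAs that averaged at most 16.1 CPM (normalised count scaled to library size) in Flag vector cells was higher in Flag-PAK5 cells: 7 mature miRNAs rose, and 0 fell. miR-199b-5p, of a family abundant in fibroblasts and other mesenchymal cells, rose from 1.01 ± 0.721 to 275 ± 149 CPM (SD, n = 3 per group). Both arms of miR-31, which restrains invasion and metastasis in breast cancer models, also rose, miR-31-5p from 0.214 ± 0.186 to 47.8 ± 22.8 CPM. miR-10b-5p, which promotes invasion in breast cancer models, rose from 16.1 ± 9.86 to 279 ± 126 CPM. miR-363-3p, from a paralog of the miR-17/92 cluster, rose from 3.56 ± 1.45 to 43.0 ± 25.8 CPM.

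The log2 fold change of miR-199b-5p was 8.01 (SE 0.75; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0130). Its summed counts were 17 and 4691, a ratio scaled by library size of 242 (95% counting interval 151 to 416). miR-31-5p had 4 counts over the Flag vector libraries and 832 over the Flag-PAK5 libraries, a ratio of 182.4 (95% interval 71.0 to 671; edgeR adjusted p = 0.0130). miR-31-3p had 0 counts in all Flag vector libraries and 106 in Flag-PAK5, at least 9.64-fold higher against a floor of 3 counts per Flag vector library (edgeR adjusted p = 0.0301). miR-199a-3p and miR-199b-3p had equal counts in every library and cannot be separated. Their shared level rose from 2.38 ± 1.01 to 62.1 ± 34.2 CPM, a log2 fold change of 4.71 (SE 0.63; edgeR adjusted p = 0.0301), so the 7 names stand for 6 distinct measurements. The miR-199a-5p arm, which is not shared, had 28 counts in Flag vector and 19 in Flag-PAK5, a ratio of 0.595 (95% interval 0.314 to 1.10). The log2 fold changes of miR-10b-5p and miR-363-3p were 4.11 (SE 0.60) and 3.62 (SE 0.56), with edgeR adjusted p-values of 0.0423 and 0.0484. Single libraries weighed on the size of these folds: without Flag vector 1 the log2 fold change was 8.80 for miR-199b-5p and 4.74 for miR-10b-5p, and without Flag-PAK5 2 it was 2.98 for miR-363-3p. miR-363-3p lost its call in 11 of 20 alternatives and miR-10b-5p in 10 of 20, and the adjusted p of miR-363-3p ranged from 3.59e-07 to 0.289. For each of the 7, every Flag-PAK5 library lay above every Flag vector library. Within the Flag-PAK5 group, library 1 was the lowest for each of them, with miR-199b-5p at 128 CPM against 270 and 426 CPM in libraries 2 and 3.

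In the GENCODE release 29 annotation, MIR199B lies in an intron of DNM1 on the opposite strand, MIR31 in an intron of the non-coding MIR31HG, and MIR10B in an intron of HOXD3 within the HOXD cluster. MIR363 neighbours MIR106A, MIR18B, MIR20B, MIR19B2 and MIR92A2. The tested main arms of these neighbours did not pass: the log2 fold changes of miR-20b-5p, miR-18b-5p, miR-19b-3p, miR-106a-5p and miR-92a-3p were 0.67, 0.65, 0.24, 0.06 and -0.34 (edgeR adjusted p from 0.520 to 0.988). miR-19b-3p and miR-92a-3p can also come from the precursors mir-19b-1 and mir-92a-1, which are not among these neighbours. Their values therefore cannot show whether the neighbours of MIR363 stayed level. The genome build behind the deposited counts is not given in the sources used here, so no coordinates are given.

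**Figure D1:**
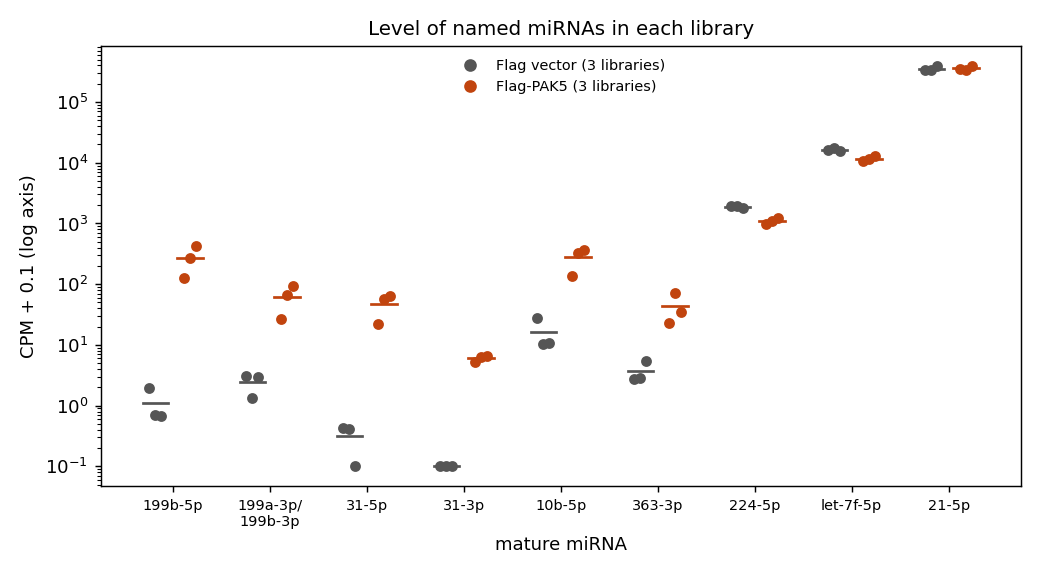
Level of named miRNAs in each library (CPM plus 0.1, log axis), with 1 point per library, Flag vector in grey and Flag-PAK5 in orange, and a bar at each group's mean. miR-199b-5p lay between 128 and 426 CPM in Flag-PAK5 and at most at 1.85 CPM in Flag vector, while miR-21-5p overlapped between the groups.

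At an unadjusted p under 0.05, edgeR gave 39 miRNAs higher and 28 lower, and 116 of the 675 (17.2%) had groups that did not overlap. The share by chance is 10% for exchangeable libraries, a value that leaves out any pairing by number. Without Flag vector 1, Flag vector 2 or Flag-PAK5 2, 0 miRNAs passed edgeR's threshold, and without Flag vector 3, Flag-PAK5 1 or Flag-PAK5 3 the counts were 4 (1 of them lower), 4 and 2, while the log2 fold change of miR-199b-5p stayed between 6.87 and 8.80 over all alternatives. With the replicate number as a block, 12 rose and 0 fell, 5 of them among the 7, and miR-10b-5p and miR-31-3p no longer passed (blocked edgeR adjusted p = 0.0712 and 0.0742, within ranges over all alternatives of 5.65e-10 to 0.215 and 2.60e-06 to 0.164). DESeq2 called 16 higher and 3 lower.

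No miRNA fell in Flag-PAK5 cells by the edgeR test, and the 5 with the smallest p among the lower ones differed modestly. miR-224-5p, encoded within GABRE, averaged 1894 ± 100 CPM in Flag vector and 1099 ± 127 CPM in Flag-PAK5, a log2 fold change of -0.79 (SE 0.14; edgeR adjusted p = 0.0662; n = 3 per group). let-7f-5p, of the let-7 family of tumour-suppressing miRNAs, averaged 16409 ± 697 and 11615 ± 1143 CPM, and miR-221-3p, which targets the cell cycle inhibitor p27, averaged 25988 ± 2785 and 19407 ± 524 CPM. Their log2 fold changes were -0.50 (SE 0.11; edgeR adjusted p = 0.112) and -0.42 (SE 0.11; edgeR adjusted p = 0.189). miR-152-3p averaged 617 ± 21.1 and 397 ± 51.3 CPM, and 1 predicted entry 175 ± 44.4 and 79.1 ± 17.1 CPM, both with an edgeR adjusted p of 0.189. With DESeq2, miR-224-5p (adjusted p = 0.00262), miR-152-3p (adjusted p = 0.0493) and that predicted entry (adjusted p = 0.0498) passed as lower, and miR-224-5p also passed with edgeR when predicted entries were left out (adjusted p = 0.0173). Over all alternatives their adjusted p-values reached 0.296, 0.611 and 0.482.

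The 5 most abundant miRNAs did not pass the test. miR-21-5p, an oncogenic miRNA in many carcinomas, averaged 355490 ± 32317 CPM in Flag vector and 358720 ± 26754 CPM in Flag-PAK5 (log2 fold change 0.01, SE 0.09; edgeR adjusted p = 0.994), and the sign of its fold turned with DESeq2's size factors. miR-100-5p, miR-30a-5p, let-7i-5p and miR-146a-5p had log2 fold changes of -0.18, -0.17, -0.27 and -0.43, with edgeR adjusted p-values of 0.771, 0.839, 0.537 and 0.366. Scaling by library total alone, without TMM factors, shifted the median log2 fold change of all tested miRNAs by 0.12, and the 7 rises also passed with that scaling.

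**Figure D2:**
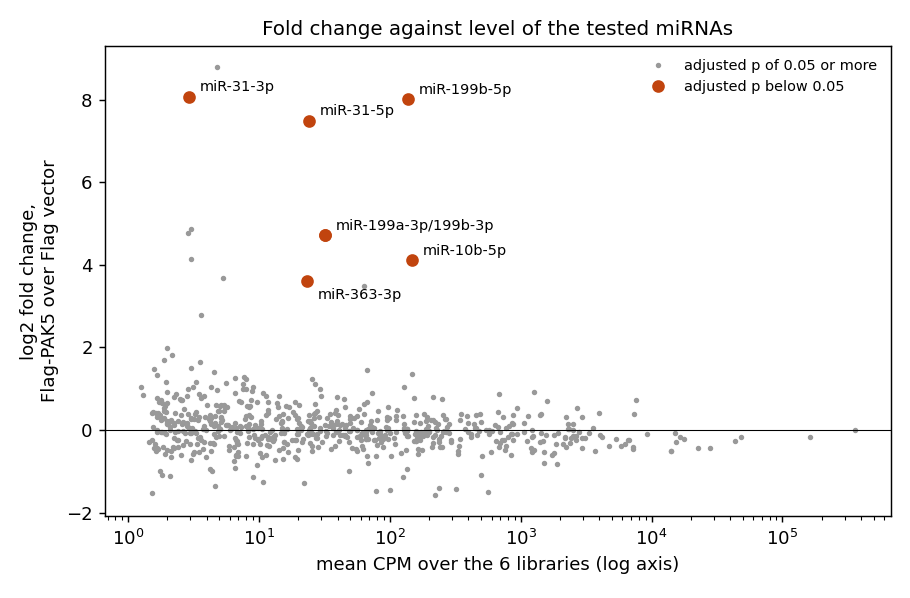
Log2 fold change of Flag-PAK5 over Flag vector (vertical axis) against mean CPM over the 6 libraries (log axis), with 1 point per tested miRNA and the 7 that passed the edgeR threshold in orange. The points that passed lie at log2 fold changes of 3.62 or more, at mean levels of at most 148 CPM.

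Among 25 lists of miRNAs fixed before the data were examined, 21 had at least 3 tested members, and 0 of them passed the camera test as a set. The rises fell into a few lists through single miRNAs. In the metastasis-suppressing list, miR-31-5p and miR-31-3p rose and the other 10 tested members did not pass, among them miR-146a-5p at 32396 ± 3998 CPM in Flag vector and 23991 ± 4104 CPM in Flag-PAK5. In the metastasis-promoting list, miR-10b-5p rose and the other 12 did not pass. In the list of stromal and smooth muscle markers, miR-199b-5p, miR-199a-3p and miR-199b-3p rose, while miR-143-3p, miR-143-5p and miR-145-5p had log2 fold changes of -1.09, -1.08 and -0.70 without passing.

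The metastasis-promoting list held miR-105-5p, which had 3 counts in Flag vector and 103 in Flag-PAK5, a ratio of 30.1 (95% counting interval 10.0 to 148). All 3 counts lay in Flag vector 2, so without that library the ratio has no finite value. It did not pass over all miRNAs (edgeR adjusted p = 0.0995) and passed with the replicate block (adjusted p = 0.0496, within a range over all alternatives of 0.00262 to 0.436). Adjusted over the list alone, 2 members of this list rose (miR-10b-5p and miR-105-5p) and 1 fell (miR-221-3p). Adjusted over the list alone, 2 members rose in the metastasis-suppressing list and 3 in the stromal list, the same members as over all miRNAs. Camera gave the metastasis-promoting list an adjusted p of 0.475 and the suppressing list 0.705. For the suppressing list the camera direction and the mean log2 fold change (1.20) were positive and the median (-0.11) was negative.

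In the let-7 family the arms lay on different sides of 0, with no member past the threshold. Of its 9 tested 5p members, 8 had a lower mean in Flag-PAK5 (median log2 fold change -0.34), and of its 11 tested 3p members, 9 had a higher one (median 0.29). 0 of the 20 passed the edgeR threshold, over all miRNAs or adjusted over the list alone, and 5 of the 5p members had an unadjusted p under 0.05. let-7b-5p averaged 3382 ± 85.5 and 2496 ± 284 CPM and miR-98-5p 1454 ± 222 and 1004 ± 90.5 CPM, with edgeR adjusted p-values of 0.265 and 0.297. Camera placed the family down (adjusted p = 0.189), with a median of -0.05 and a mean of 0.04. Of 7 tested members of the miR-200 family and miR-205, which maintain the epithelial state, 6 were lower and 0 passed. miR-200b-3p averaged 698 ± 64.1 and 486 ± 34.6 CPM, miR-429 averaged 69.2 ± 13.5 and 53.3 ± 7.12 CPM, and miR-200c-3p averaged 41.4 ± 7.42 and 30.2 ± 2.34 CPM, with edgeR adjusted p-values of 0.265, 0.685 and 0.589. Camera gave this list an adjusted p of 0.102.

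The smallest camera adjusted p, 0.0579, belonged to the stromal markers and to the placental C19MC and miR-371-373 clusters, both upward. All 4 tested members of the C19MC list had higher means and 0 passed. In the miR-17/92 and paralogous clusters, 1 of 21 members rose, miR-363-3p, and camera gave an adjusted p of 0.185. The camera adjusted p was also 0.185 for the neural markers (5 members, upward) and the miR-181 family (9, downward). It was 0.296 for the cluster of miR-183, miR-96 and miR-182 (3 members) and 0.396 for the clusters of miR-23, miR-24 and miR-27 (11). The miR-29 family (7 members), the miR-15/16 family (12), the blood cell markers (5) and the liver and gut markers (4) each had 0.475. The Drosha-independent miRNAs (8 members) had 0.610, the miR-34 and miR-449 family (6) 0.764 and the miR-30 family (11) 0.804. Entries overlapping other structural RNAs (9) had 0.961, and the miR-99, miR-100 and miR-125 families (10) 0.983. Apart from the stromal and miR-17/92 lists, each of these had 0 members past the threshold over all miRNAs, and the same 0 adjusted over the list alone except in the miR-99, miR-100 and miR-125 families. The signs of median, mean and camera differed for the miR-34 and miR-449 family (median -0.01, mean 0.02, downward), the miR-30 family (median -0.07, mean 0.06, downward) and the miR-99, miR-100 and miR-125 families (median -0.01, mean 0.17, upward).

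A line of the extraction protocol in the labels names retinas as the tissue. The list of retina markers had a camera adjusted p of 0.960 (downward, with a median of 0.17 and a mean of 0.22), and 0 of its 5 members passed over all miRNAs. Adjusted over the list alone, miR-204-5p rose, at 1.53 ± 0.654 CPM in Flag vector and 4.51 ± 1.01 CPM in Flag-PAK5. In the miR-99, miR-100 and miR-125 families, miR-100-3p rose and miR-99b-5p fell when adjusted over the list alone. The fry test for change in either direction, which does not compare a list with other miRNAs, passed for 8 of the 21 lists: both metastasis lists, the stromal and retina markers, the miR-17/92 clusters, let-7, the miR-34 and miR-449 family, and the miR-99, miR-100 and miR-125 families (adjusted p from 0.000447 to 0.0171). The fry test for 1 direction passed for 0 (smallest adjusted p = 0.137). With an estimated correlation the smallest camera adjusted p over the 21 lists was 0.725. The stromal list passed camera when a mean of at least 10 CPM was required (adjusted p = 0.0166), without Flag-PAK5 2 (adjusted p = 0.0459) and, together with the miR-17/92 list, without Flag vector 1 (adjusted p = 0.00942 for both). The stromal list holds miR-199a-3p and miR-199b-3p as 2 members, although their equal counts are 1 measurement. With miR-199, miR-31, miR-10b and miR-363 left out, the camera direction of the stromal list was downward (adjusted p = 0.356). The luminal breast markers, the muscle markers, the DLK1-DIO3 cluster and the miR-506-514 cluster had 2, 2, 1 and 0 tested members and were not tested as sets.

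**Figure D3:**
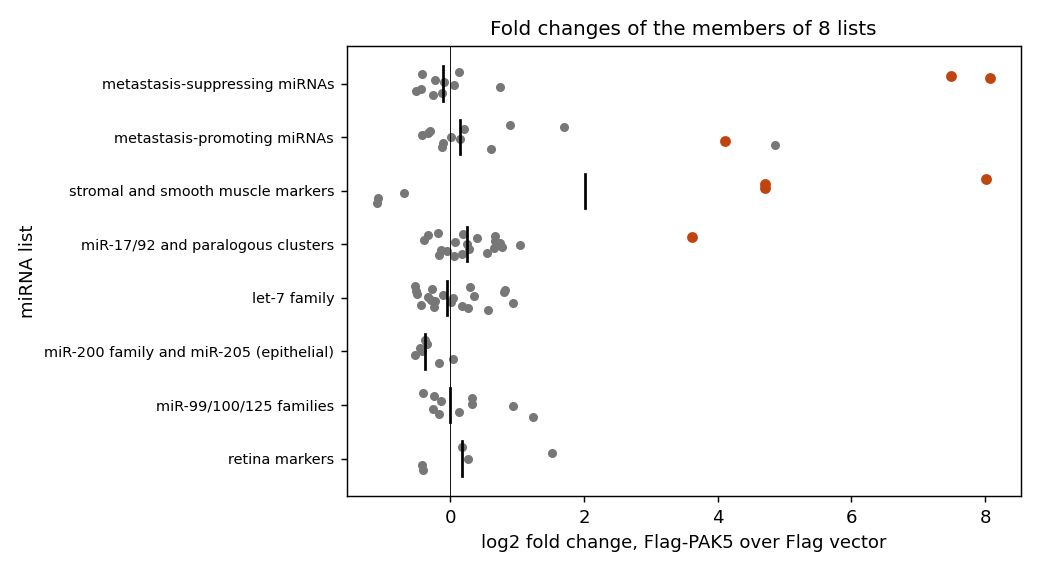
Log2 fold change of Flag-PAK5 over Flag vector for each tested member of 8 lists (1 point per mature miRNA, orange where it passed the edgeR threshold), with a black bar at each list's median. The orange points lie far from the medians of the metastasis-suppressing (-0.11), metastasis-promoting (0.15) and miR-17/92 (0.24) lists. In the stromal list 3 of 6 members are orange, and its median of 2.01 lies between the orange and the grey points.

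The ratio of 5p to 3p counts changed for 2 of 134 precursors, and for 1 of them, mir-199b, the counts do not isolate 1 hairpin. For mir-199b, the log2 ratio of 5p to 3p counts moved from -1.22 ± 0.742 in Flag vector to 2.17 ± 0.114 in Flag-PAK5 (SD, n = 3 per group), a difference of 3.39 (SE 0.38; limma adjusted p = 0.00243). Its 3p counts are shared with miR-199a-3p, so in Flag vector cells the ratio includes 3p tags that mir-199a can supply. Flag vector had 28 counts of miR-199a-5p and 17 of miR-199b-5p. A rise of mir-199b alone could thus move this ratio, so it cannot show a change in arm balance. For mir-100, whose 5p arm is among the 5 most abundant miRNAs, the log2 ratio moved from 13.46 ± 0.0972 to 12.07 ± 0.312, a difference of -1.39 (SE 0.26; limma adjusted p = 0.0475). miR-100-3p averaged 15.2 ± 1.35 and 35.9 ± 7.19 CPM. let-7i, next by p, did not pass (difference -1.10, SE 0.29; limma adjusted p = 0.212). It passed when both arms needed a mean of at least 10 CPM (limma adjusted p = 0.0345, within a range over all alternatives of 0.0345 to 0.494).

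The fold changes of both arms had the same sign for 69 of the 134 precursors (51.5%), and 17 precursors had an unadjusted p under 0.05. With the replicate block 1 precursor passed: mir-199b held (adjusted p = 0.0336) and mir-100 did not (adjusted p = 0.124, within a range over all alternatives of 0.00433 to 0.234). Leaving out Flag vector 1 or Flag vector 3 left 1 precursor, mir-199b. mir-100 also lost its call without Flag vector 2, Flag-PAK5 1 or Flag-PAK5 2.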

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

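The alternatives that sum precursor lines, leave out predicted entries, merge names with equal counts, drop both libraries numbered 3 or leave called families out of the lists were chosen after the results were seen. The count of 7 miRNAs, all higher, became 12 with the replicate block, 19 with DESeq2 (3 lower), 15 without a filter on low counts (1 lower), 17 without predicted entries (1 lower) and 4 with equal counts merged, and ran from 0 to 4 over the fits that leave out 1 library (1 lower without Flag vector 3). Apart from the block, each of these fits also tested another number of miRNAs than 675 (1052 with DESeq2, 1625 without a filter, 475 without predicted entries, 667 with equal counts merged, 710 to 722 without 1 library), and the cause of the changes was not tested. Every other alternative gave between 5 and 10, all higher, except 6 higher and 1 lower without both libraries numbered 3. The log2 fold changes of the 7 stayed positive in each alternative that gave one: 20 apiece, but 19 for miR-31-3p (below the 10 CPM filter) and for miR-199b-3p (merged with miR-199a-3p). No list passed in the planned camera test (8 of 21 did with fry for change in either direction), and 1 did when a mean of at least 10 CPM was required, with a range of 0 to 2 over the fits without 1 library. The arm ratio count of 2 became 1 with the block, 3 each with a pseudocount of 5, a mean of at least 10 CPM or without both libraries numbered 3, and 1 to 3 over the fits without 1 library. mir-199b passed in all 10 alternatives, each with 3p counts that it shares with miR-199a-3p. Apart from the 7 miRNAs it added and the loss of miR-10b-5p, miR-31-3p and mir-100, the block changed no call. The log2 fold change of miR-21-5p, 0.01, turned to -0.014 with DESeq2's size factors in edgeR and to -0.0075 with DESeq2, and ran from -0.048 to 0.10 without 1 library. Fewer libraries leave fewer degrees of freedom. For the named miRNAs and precursors, 420 values kept their direction and side of the threshold, 51 no longer passed, 9 passed anew and 6 turned sign. Depth limits the rare miRNAs most: Flag vector 3 had 3630276 counts, so 1 count there stood for about as much as the levels of miR-31-5p in the Flag vector libraries.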

Other observations

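The tests of stromal cells, of 1 other cell source, of shared miR-199 reads and of HOX location were chosen only after the results they concern had been seen. Several miRNAs outside the naming rule had far lower counts in Flag vector than in each Flag-PAK5 library, without passing edgeR's threshold. miR-196a-5p, encoded in the HOXB and HOXC clusters, had 0 counts in Flag vector and 169 in Flag-PAK5, at least 15.8-fold higher against 3 counts per Flag vector library (edgeR adjusted p = 0.0662). miR-196b-5p, encoded within HOXA9, had 13 and 178 counts (ratio 12.0, 95% counting interval 6.85 to 23.0; edgeR adjusted p = 0.0995). miR-615-3p, encoded in an intron of HOXC5, averaged 10.4 ± 5.41 and 117 ± 68.3 CPM (edgeR adjusted p = 0.0634, and 0.0178 with the replicate block). With miR-10b-5p these make 4 of the 7 tested miRNAs of the HOX clusters that were at least 8-fold higher in Flag-PAK5, against 9 of the 668 others (Fisher's exact test, 2-sided p = 2.83e-06). The exceptions were miR-10a-5p, at 3437 ± 394 and 3271 ± 85.7 CPM, miR-10a-3p and miR-7704. Of the 4, only miR-10b-5p passed edgeR's threshold. Fisher's test treats miRNAs as independent, so its p does not measure the spread between libraries. That location in the HOX clusters goes with these higher levels is a hypothesis, noticed and tested on the same 6 libraries.

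miR-105-5p and miR-767-5p, neighbours within an intron of GABRA3, rose together from trace levels under the replicate block. Neither passed in the main edgeR test. Without the block, miR-105-5p passed with DESeq2 (adjusted p = 0.00262) and with edgeR without a filter on low counts (adjusted p = 0.00578). miR-767-5p had 3 counts in Flag vector, all in library 2, and 98 in Flag-PAK5 (ratio 28.7, 95% counting interval 9.52 to 141, blocked edgeR adjusted p = 0.0496). miR-155-5p went the other way, with 76 counts in Flag vector (42, 34 and 0 per library) and 8 in Flag-PAK5. The ratio was 0.0923 (95% counting interval 0.0385 to 0.191). It did not pass the filter on low counts and so was not tested. miR-451a, a marker of red blood cells, had 3170 counts in Flag vector 3 and 72 to 976 in the other libraries. miR-1-3p, a muscle miRNA, had 137 counts in Flag-PAK5 3 and 4 to 35 elsewhere.

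In Flag-PAK5, 13 mature miRNAs (12 distinct profiles) were at least 8-fold higher. After all libraries were thinned to 3630276 counts, 10 of the 13 stayed at least 8-fold higher. Thinning leaves the expected fold in CPM unchanged, so it says little about depth. A depth difference between the groups is argued against by their mean totals, 5524700 counts in Flag vector and 5786900 in Flag-PAK5. Stromal cells are argued against: the stromal markers miR-199a-5p and miR-214-3p together had a ratio of 0.490 (34 and 19 counts, 95% interval 0.264 to 0.884), with the more abundant stromal miR-143-3p at 684 ± 396 CPM in Flag vector and 321 ± 87.4 CPM in Flag-PAK5. Over Flag-PAK5 libraries 1, 2 and 3 the mean profile of the set was 1, 2.59 and 2.40, and the residual SD around it on the log2 scale was 0.285, at the 3.01 percentile of 10000 random sets matched on level (5th to 95th percentile 0.317 to 0.873). The set holds both arms of mir-31 and of mir-199b, and the neighbours miR-105-5p and miR-767-5p. Such members can vary together for that reason alone, and the random sets were matched on level only. Another cell population at a different share in each Flag-PAK5 library may account for the shared profile, as may a graded response to PAK5, and neither is singled out: miR-31-3p was nearly level (5.07, 6.23 and 6.38 CPM) where miR-31-5p, from the same hairpin, was not (21.7, 57.8 and 64.0 CPM). The rise of miR-199a-3p may be that of miR-199b alone, since both 3p arms have equal counts and miR-199a-5p had a ratio of 0.595 (95% interval 0.314 to 1.10).

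Both libraries numbered 3 deviated from their groups in the same direction, with a correlation over miRNAs of 0.648. Their lower depth is argued against, since the correlation was 0.680 after thinning to equal totals. Without predicted entries, whose share was 8.80% in Flag vector 3 and 7.19% in Flag-PAK5 3, the highest in each group, it was 0.323. That is about midway between none and the full value, so whether predicted entries carry the shared deviation cannot be told apart from a wider cause. The labels give no batch, and no biological explanation was tested.

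The 5p to 3p ratio was lower in Flag-PAK5 for 11 of 11 let-7 precursors, with a median log2 change of -0.81, although some share a 5p arm and are not independent. As a group, the other 123 precursors moved the same way but less. Of these, 83 had a lower ratio of abundant to rare arm, mir-100 among them. The median change over the 123 was -0.14 (95% bootstrap interval -0.27 to -0.08). Within these libraries, a compression of equal size in all precursors is argued against, since this interval lies above the let-7 median. The let-7 median also lay at the 0.03 percentile of 10000 sets matched on the arm ratio, whose median was -0.34. The bootstrap interval and these sets treat precursors as independent, so neither the interval nor the percentile measures the spread between libraries. A part played by a general compression stays open. The mean log2 ratio over the 11 was 7.96 ± 0.12 in Flag vector and 7.27 ± 0.36 in Flag-PAK5 (SD, n = 3 per group; exact permutation p = 0.1, 2-sided, and 0.25 with the pairs by number kept, each the smallest it can give). A shift in let-7 processing or stability with PAK5 may be a source, as may reads shared between near-identical let-7 members, and neither was tested.

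With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7 miRNAs and the highest of the others 0, so 1 of the 10 gave as many. For arm ratios the real split gave 2 precursors and the highest other 0, again 1 of 10. For the lists the real split gave 0 and the highest other 3, so all 10 gave as many. Of the 10 splits, 4 part the libraries of every number, as the real one does, and the other 3 of these gave 0 miRNAs, 0 precursors and at most 3 lists. The remaining 6 keep both libraries of some number together, and they too gave 0 miRNAs, 0 precursors and at most 3 lists.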
